A study of Caenorhabditis elegans with 2 samples.

How the data were processed

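Whole L4 larvae of strain OP18, carrying LIN-39 tagged with enhanced green fluorescent protein, were profiled by ChIP-seq in 2 biological replicates with library size range 150 to 350 bp, per the labels. The replicate numbers were taken from the labels. Both samples form 1 group, so no test between groups was made.

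The authors deposited 4 peak lists on each of 2 genome builds, ce10 and ce11. Per the deposited text descriptions, each replicate's list came from that replicate's alignment and a control alignment, the same control file for both replicates on a build, and the pooled list came from both alignments with that control. The thresholded list was derived from the pooled and replicate lists as peaks past an irreproducible discovery rate threshold. The aligner, the peak caller, the threshold and their versions are not given in the sources used here. The deposited signal value of each region is the caller's enrichment over the control, and its size is not comparable between lists, so it was used for ranks and for the ratio to the median of its own list (relative signal). The deposited q column, by the format's convention −log10 of a q-value, reached below 0 in the pooled lists and was treated as a score. Another column of the lists held a single placeholder value and was not used. No counts or depths were given, so the depth of each replicate is unknown.

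Coordinates are on ce11 and 1-based, and were annotated with the matching reference and Ensembl release 115, after checking that no region ran past the end of its chromosome. The ce10 lists were used for numbers, chromosome names, signals and replicate agreement within that build, and no coordinates were converted. A thresholded peak was compared with the remaining pooled candidates, which could have passed the threshold. Regions with summits within 200 bp that were each other's nearest were taken as the same region. Promoters ran from 1000 bp upstream to 200 bp downstream of a protein-coding gene's 5' end. Gene lists were tested on genes whose 5' end was the nearest to a summit and at most 5000 bp away, and 1033 of 1046 list symbols were matched to the annotation. Motifs were searched on both strands within 100 bp of the summit and in 2 flanks of 100 bp centred 500 bp away.

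Shares were compared with two-sided Fisher's exact tests, centre and flank with exact McNemar tests, and the top regions of the replicates with a one-sided Fisher's exact test. Rank correlation was tested with 100000 permutations, or 2000 for its alternatives. Benjamini-Hochberg adjustment was made within each family, over 6 feature classes, 6 chromosomes, 19 gene lists, 9 patterns and 6 small RNA classes, with a threshold of 0.05. Regions share reads and some lie close together (2 pairs of peaks have overlapping intervals), so p-values over regions describe these lists and not the spread between animals. The genes named in the text are the nearest protein-coding gene of each of the 20 highest peaks, the up to 3 genes of highest signal of each list, the 6 Hox genes and *unc-119*, and other names were chosen after their values were seen. The tests, the gene lists, the 9 patterns and most alternatives were fixed before the data were examined. Alternatives varied the distance and overlap rules, the number of top regions, the promoter, gene, motif and tRNA distances, the background, the build and the replicates used.

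The functions were tested on simulated data. With 40 planted shared regions among 3000, the agreement test passed in 100% of 200 runs, and with none in 6.5%. A planted list of 7 genes among 13000 was called in 100% of 100 runs. The ribosomal protein list also had 7 members near a peak. Smaller planted numbers were not simulated, so the power for the other lists, with 0 to 3 members, is unknown. The motif test found 30 planted sites among 163 regions in 99% of 100 runs against 4% with none. The simulated centres and flanks had the same base composition, unlike those of the peaks. The 4% therefore does not cover pattern differences that come from GC content. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.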

Results

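The series profiled where LIN-39, a Hox homeodomain protein that patterns the mid-body of *Caenorhabditis elegans*, lies on the genome of L4 larvae. LIN-39 is known for its roles in the vulval precursor cells, the ventral cord neurons and the postembryonic mesoderm. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was run on whole animals of mixed sex from strain OP18, which carries a transgene expressing LIN-39 fused to enhanced green fluorescent protein in an *unc-119* mutant background. There were 2 samples, the biological replicates of 1 group, so the design held no contrast between conditions, tissues or stages. The comparisons were those between the replicates, and those between the peaks that passed the authors' threshold and the remaining regions of the pooled list. By its deposited name that list holds peaks and background, so the remaining regions are not taken as weaker binding sites. The files gave no read counts, so the depth of each replicate is unknown. Intervals on shares of regions are 95% Wilson intervals that cover counting error over regions, which are not replicates of the experiment.

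On genome build ce11 each replicate's list and the pooled list held 30000 regions, and the authors' thresholded list held 163 peaks, each 344 bp wide. The thresholded list consisted of the 163 regions of highest signal in the pooled list, with signals from 39.2 to 190.5 against a pooled median of 16.7. On build ce10 the thresholded list held 103 peaks, again exactly the highest pooled regions, so ce11 gave 1.58 times as many peaks. Of the 163 peaks, 27 had a q-column score over 1.3 and 60 had one under 0.3.

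The strongest peaks lay in both replicates, and agreement fell off quickly below them. The peak of highest signal lay on chromosome X from 11094046 to 11094389, in intergenic sequence with its summit 3968 bp from the 5' end of *W02H3.3*. Its signal was 10.01 ± 2.42 times the list median (SD, n = 2), and it ranked 2 in replicate 1 and 1 in replicate 2. The next peaks lay on X in intergenic sequence nearest to *K02D3.1*, 6054 bp from its 5' end, with a relative signal of 8.59 ± 0.329 (SD, n = 2), and on X in an intron of *Y41G9A.17*, with 7.51 ± 4.69 (SD, n = 2). The fourth lay on chromosome II from 10563406 to 10563749, in the promoter of *cdc-48.1*, which encodes a AAA ATPase, and had a relative signal of 7.28 ± 4.16 (SD, n = 2). Peaks nearest to *F22H10.2*, *nspc-17* and *ZK899.6*, all on X, ranked 5, 6 and 7 in the pooled list. A peak 698 bp upstream of *egg-5* on chromosome I, a gene of the oocyte-to-embryo transition, ranked 8 and had a relative signal of 5.89 ± 2.49 (SD, n = 2). The peak at rank 11 lay on X 4966 bp upstream of *xol-1*, the switch gene of sex determination and dosage compensation, with 5.29 ± 0.568 (SD, n = 2). The other genes nearest to the 20 highest peaks were *rpl-3*, *T27A8.7*, *rpl-35*, *F19H6.5*, *Y17G9B.5*, *ugt-50*, *algn-10*, *tub-2*, *T28F12.1*, *rpl-15* and *ins-39*, with relative signals from 3.91 ± 1.72 to 5.58 ± 1.63 (SD, n = 2).

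Of the 163 highest regions in each replicate, 55 were shared, which is 33.7% (26.9 to 41.3%), where 1.85 would be shared by chance among the 8768 regions found in both lists (one-sided Fisher's exact test, p = 3.0e-71). Over those 8768 regions the signals of the replicates correlated weakly, with a Spearman rho of 0.130 across regions, at the smallest p that 100000 permutations can give, 1e-05. Of the 163 thresholded peaks, 159 had a region within 200 bp in both replicate lists and 4 had none in replicate 1. The median peak lay at signal percentile 99.63 of the list of replicate 1 and 99.66 of that of replicate 2, but the lowest-ranked peaks lay at ranks 22571 and 14051, and 118 peaks, or 72.4% (65.1 to 78.7%), were among the 1000 highest regions of both. The thresholded peaks were themselves selected from these 2 replicates, pooled and by their reproducibility. Their presence and high ranks in each replicate therefore follow in large part from the selection and are no independent measure of agreement. Both replicates were called against the same control file, which can raise their agreement.

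**Figure D1:**
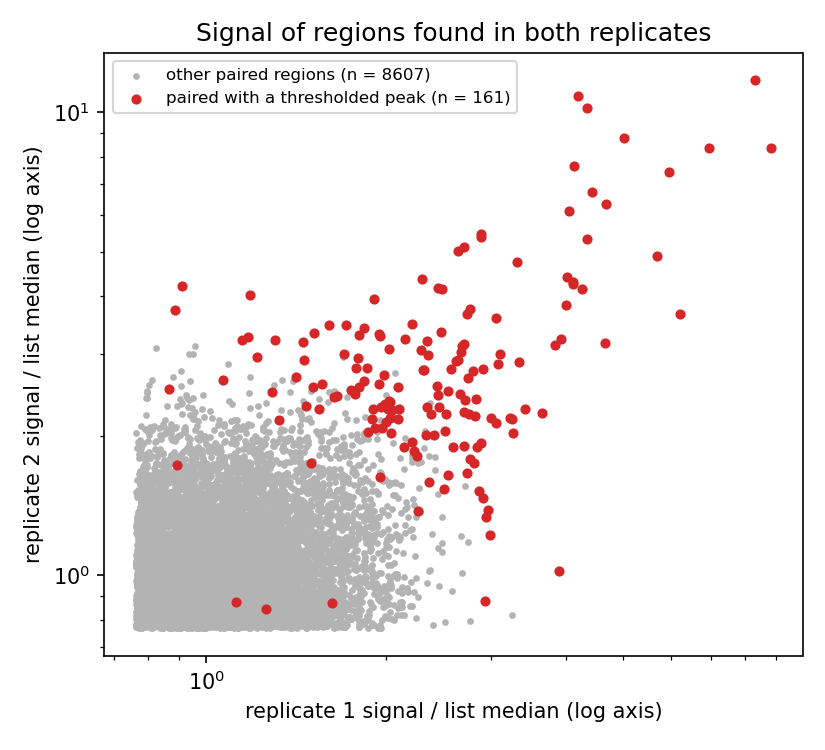
Signal of each region divided by the median of its list, in replicate 1 (x, log axis) against replicate 2 (y, log axis), for the 8768 regions with summits within 200 bp. In red are the 161 pairs whose replicate 1 summit lay within 200 bp of the summit of a thresholded peak, so a peak can match more than 1 pair. These reach the upper right, and the 8607 other pairs, in grey, form a cloud around the medians.

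Peaks lay at promoters more often than the remaining candidates did, and less often in coding sequence. A summit between 1000 bp upstream and 200 bp downstream of a protein-coding gene's annotated 5' end was found for 69 of the 163 peaks, or 42.3% (35.01 to 50.01%), against 22.5% of the 29837 remaining pooled candidates, an odds ratio of 2.54 (1.83 to 3.50; two-sided Fisher's exact test, p = 1.6e-08). Of 10000 random genome positions, 22.2% lay in a promoter, so in this respect the candidates were close to the genome at large. Coding exons held 2 peaks, 1.23% against 15.8% of candidates (two-sided Fisher's exact p adjusted over 6 classes = 4.5e-09). These were the peaks nearest to *henn-1* and *dct-9*, named here because the count was small. The coding exon share was 7.36% with the regions of replicate 1 alone and 8.3% over the 1000 highest pooled regions, below the candidates in both (Fisher's exact adjusted p = 0.00041 and 1.7e-11). Introns held 22.1% against 31.8% (Fisher's exact adjusted p = 0.0138), and intergenic sequence 30.7% against 25.8% (adjusted p = 0.184). Each summit was counted only in the first class that applied, with promoter first. The higher promoter share of the peaks therefore left less for the other classes. Intron and intergenic shares were not compared among summits outside promoters, so these values show neither depletion nor its absence there. The 5' UTR share was 2.45% against 0.751% (Fisher's exact adjusted p = 0.0543) and the 3' UTR share 1.23% against 3.33% (adjusted p = 0.184). The intron share did not pass the test with the regions of replicate 1 alone, at 25.8% (Fisher's exact adjusted p = 0.180), or over the 1000 highest pooled regions, at 29.5% (p = 0.144), where the intergenic share passed it at 29.7% (p = 0.0117).

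**Figure D2:**
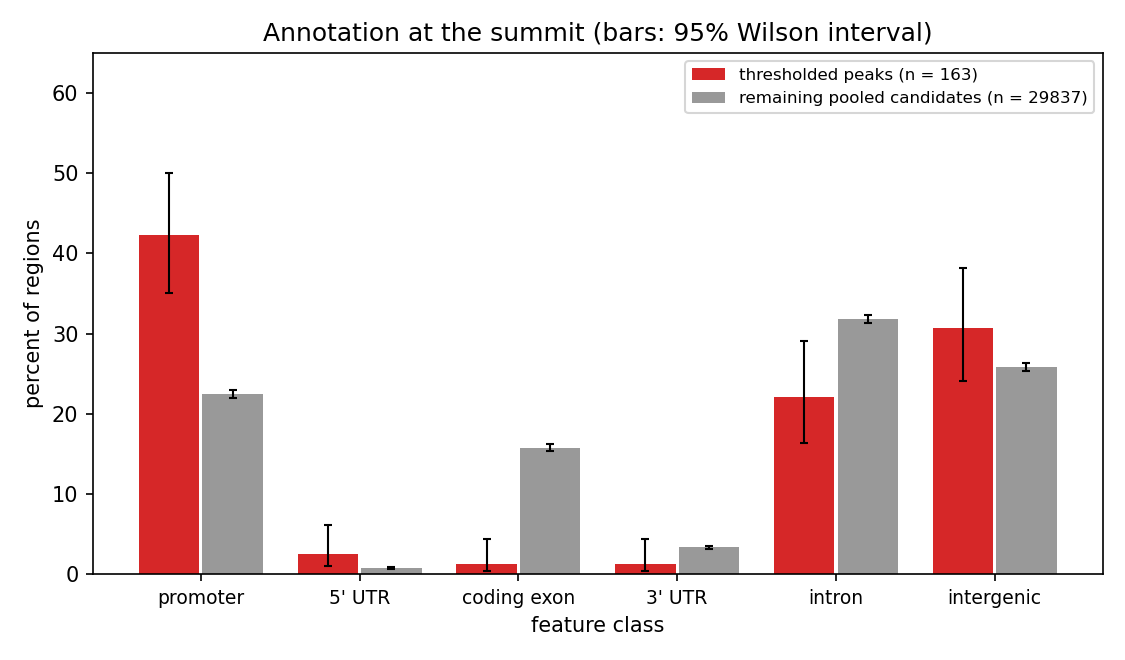
Percent of summits (y) in each feature class (x) for the 163 thresholded peaks in red and the 29837 remaining pooled candidates in grey, with 95% Wilson intervals. Promoters stand at 42.3% against 22.5%, and coding exons at 1.23% against 15.8%.

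Chromosome III, which carries *lin-39*, held more peaks than the candidates did and chromosome V fewer. III held 33 of the 163 peaks, 20.2% (14.8 to 27.1%) against 12.3% of candidates (two-sided Fisher's exact p adjusted over 6 chromosomes = 0.0117), and V held 17, 10.4% (6.61 to 16.1%) against 20.7% (adjusted p = 0.0039). X held 45 peaks, 27.6% (21.3 to 34.9%) against 21.1%, which did not pass the test (Fisher's exact p = 0.0537, adjusted p = 0.092). Chromosomes I, II and IV did not pass it either. The central part of each chromosome held 57.7% of peaks and 56.8% of candidates (Fisher's exact p = 0.874). The calls for III and V were lost with replicate 1 alone, at 16.6% (Fisher's exact adjusted p = 0.093) and 14.7% (adjusted p = 0.064), and the call for X was gained with replicate 2 alone, at 28.8% (adjusted p = 0.0322), and with the peaks in the top 1000 of both replicates, at 33.1% (Fisher's exact adjusted p = 0.0091), a setting chosen after seeing the data. Over the 1000 highest pooled regions neither III, at 12.6%, nor V, at 18.1%, passed the test (Fisher's exact adjusted p = 0.807 and 0.0765).

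**Figure D3:**
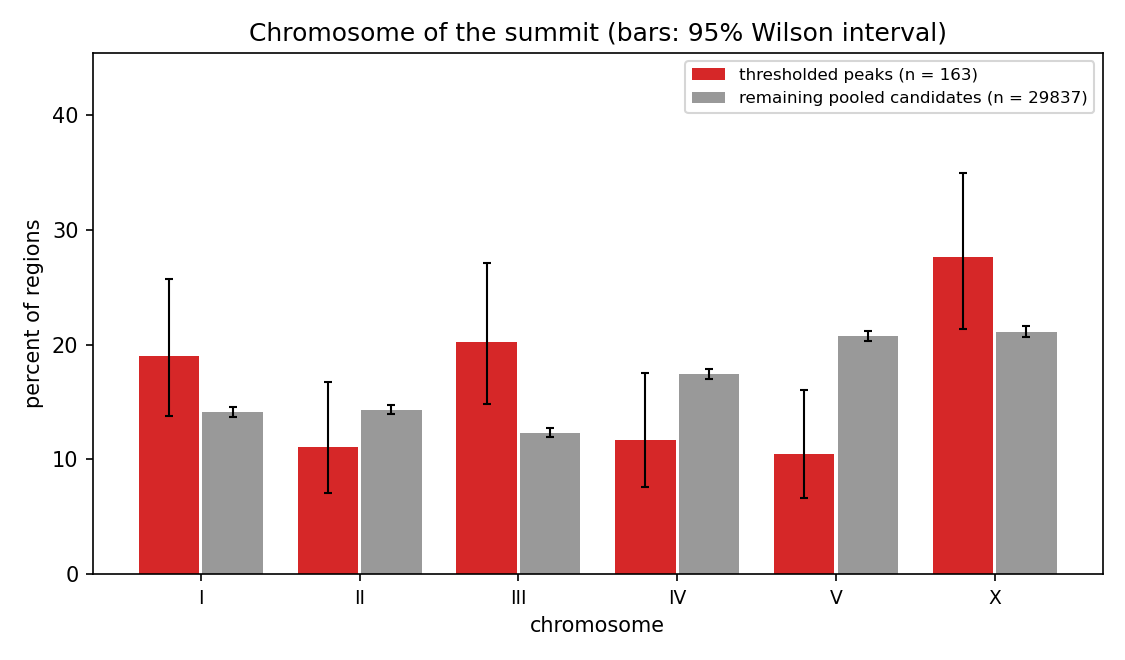
Percent of summits (y) on each chromosome (x) for the 163 thresholded peaks in red and the 29837 remaining pooled candidates in grey, with 95% Wilson intervals. III stands at 20.2% against 12.3%, V at 10.4% against 20.7% and X at 27.6% against 21.1%.

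Among 19 gene lists fixed in advance, ribosomal protein genes stood out near the peaks, followed by pan-neuronal genes. No list of known LIN-39 tissues passed the test, which could not tell absence from enrichment in lists of this size. The nearest protein-coding gene was counted where its 5' end lay within 5000 bp, which gave 13127 genes near any candidate. Ribosomal protein genes made up 4.93% of the genes near a peak, 7 of the 39 such genes near any candidate, and 0.246% of the other genes, an odds ratio of 20.96 (7.67 to 49.5; two-sided Fisher's exact test, p adjusted over 19 lists = 3.3e-06). They were *rpl-3*, *rpl-35*, *rpl-15*, *rpl-11.2*, *rps-15*, *rpl-12* and *rps-28*, each with its peak in the promoter. The *rpl-3* peak lay on III from 3867402 to 3867745, 280 bp upstream of the gene, with a relative signal of 5.58 ± 1.63 (SD, n = 2). The *rpl-35* peak lay on III from 7854534 to 7854877, with 5.09 ± 1.47 (SD, n = 2), and the *rpl-15* peak on IV from 654751 to 655094, with 3.92 ± 0.112 (SD, n = 2). The *rpl-12* peak ranked 44 in replicate 2 and 2446 in replicate 1.

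The pan-neuronal list had 3 of 20 members near a peak, *unc-18*, *unc-44* and *unc-64* (odds ratio 16.4, 3.05 to 57.8; Fisher's exact adjusted p = 0.0117). *unc-18* and *unc-64* encode the Munc18 and syntaxin proteins of synaptic vesicle release, and *unc-44* an ankyrin. Their relative signals were 2.49 ± 0.377, 2.33 ± 0.0235 for *unc-44* and 2.27 ± 0.456 for *unc-64* (SD, n = 2). With replicate 2 alone this list had 1 member (Fisher's exact adjusted p = 0.482), and with the upper part of the peaks, split at the median signal, also 1 (adjusted p = 0.283). The Wnt pathway list had 2 members, the Dishevelled gene *mig-5* at 3.32 ± 0.375 and the neuroblast migration gene *mig-13* at 2.56 ± 0.138 (SD, n = 2; Fisher's exact p = 0.0275, adjusted p = 0.174), and 3 when the nearest gene on both sides was taken (Fisher's exact adjusted p = 0.0216). Single members of other lists were *lin-53*, *hsp-1* (in 2 lists), *his-37* and *nhr-19*, and the homeobox list had *ceh-5* and *ceh-38*, none past the test. The *ceh-38* peak ranked 25 in replicate 2 and 19666 in replicate 1, and the *his-37* peak had no region in the list of replicate 1. The lists for Hox genes and cofactors, vulval development, ventral cord neurons, mesoblast and muscle, pharynx, epidermis, intestine, germline, heterochronic genes and collagens had 0 members near a peak (Fisher's exact adjusted p = 1 for each). Each nearest gene was assigned by distance alone.

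Within 100 bp of the summit, GAGAGA was the pattern of the 9 that passed the flank test, and the Hox patterns did not pass it at the 163 peaks. GAGAGA was present at 59 of 163 peaks, or 36.2% (29.2 to 43.8%), against 8.59% in flanks of the same length centred 500 bp away (exact McNemar test, two-sided, p adjusted over 9 patterns = 5.1e-09) and 10.3% of remaining candidates. The control pattern CAGCTG was present at 6.75% against 1.23% (exact McNemar p = 0.0225, adjusted p = 0.101), and base composition, with a GC content of 42.3% at the centres and 36.4% in the flanks, was not adjusted for. The composite site of Hox proteins and their PBC partners, TGATNNATKR, was present at 12 peaks, 7.36% (4.26 to 12.4%), against 4.29% in the flanks (exact McNemar p = 0.359, adjusted p = 0.539) and 5.03% of candidates (Fisher's exact p = 0.204). The same letters in reverse order were present at 0.613%, against 1.23% in the flanks and 1.95% of candidates. That reversed pattern was thus rarer than the composite site in flanks and candidates too. Over the 1000 highest pooled regions the composite site was present at 7.40% and passed the flank test (exact McNemar adjusted p = 0.0355). The homeodomain core TAATKR was present at 28.2%, against 34.97% in the flanks (exact McNemar adjusted p = 0.411) and 40.4% of candidates (Fisher's exact p = 0.0017, adjusted p = 0.0051). Its letters in reverse order were present at 28.2% too, against 37.4% in the flanks and 36.3% of candidates (Fisher's exact p = 0.0336, adjusted p = 0.0755). With a window of 200 bp the TAATKR share of 46.6% lay below the flanks past the test (exact McNemar adjusted p = 0.0035). TGATAA was less frequent than in candidates, at 9.20% against 19.2% (Fisher's exact adjusted p = 0.0029), but not against the flanks, at 16.6% (exact McNemar adjusted p = 0.237). TGACAG, bound by MEIS-class partners, was present at 9.82% against 9.20% in the flanks (exact McNemar adjusted p = 1).

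**Figure D4:**
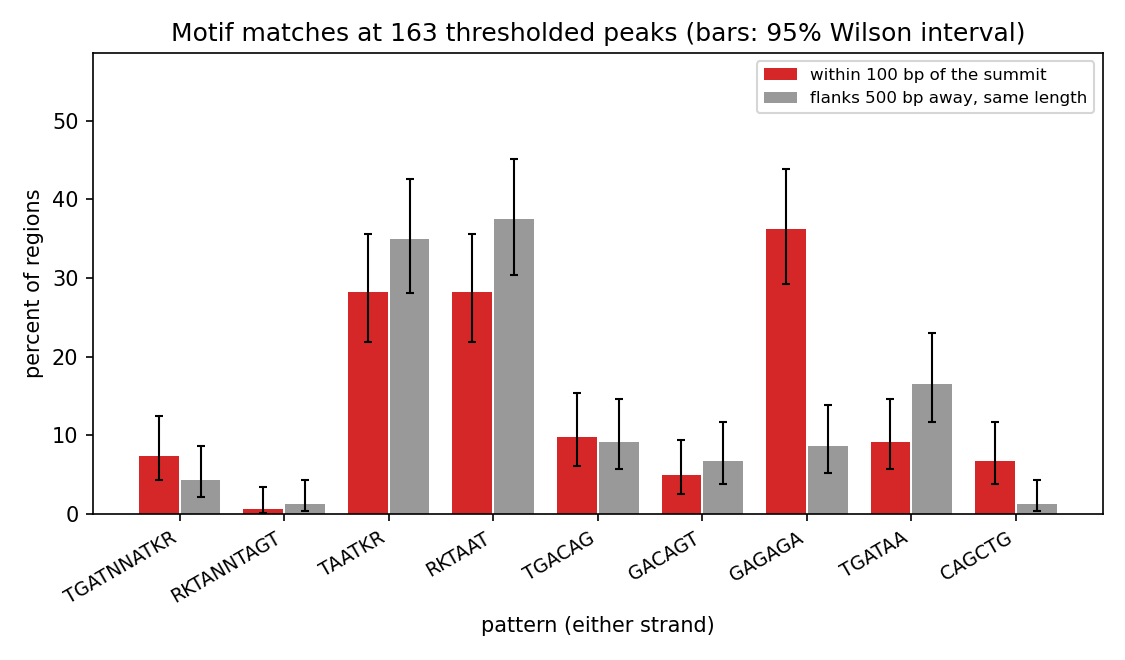
Percent of the 163 thresholded peaks (y) with a match to each pattern (x) within 100 bp of the summit in red and in flanks of equal length 500 bp away in grey, with 95% Wilson intervals. GAGAGA stands at 36.2% against 8.59%, and TGATNNATKR at 7.36% against 4.29%.

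Highly transcribed tRNA genes, a known source of unspecific ChIP-seq signal, lay within 200 bp of 2 of the 163 peaks, 1.23% (0.337 to 4.36%), against 0.352% of candidates (two-sided Fisher's exact test, p = 0.115). Over the 1000 highest pooled regions the share was 0.9% and passed the test (Fisher's exact p = 0.0096).

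No Hox gene had a thresholded peak nearby. The *lin-39* gene lies on III from 7528641 to 7536632, and its nearest thresholded peak was 318074 bp away. No candidate lay within 10000 bp of it in the pooled list or either replicate's list, where the median of 10000 random windows on III was 7. Within 20000 bp there were 4 pooled candidates against a median of 13, at percentile 1.72 of the windows. Within 50000 bp the counts were no longer unusual, with 22 pooled candidates against a median of 29, at percentile 21.1, and percentiles of 32.2 and 23.8 in replicates 1 and 2. The stretch without a candidate ran from 7516254 to 7559356 in the pooled list, 43102 bp, and also held the Hox gene *ceh-13*. Around *unc-119*, 12 pooled candidates lay within 20000 bp, at percentile 47.9. The strongest pooled candidates near the other Hox genes had relative signals of 1.43 for *ceh-13*, 1.27 for *mab-5*, 1.42 for *nob-1* and 1.08 for *php-3*, and *egl-5* had 0 pooled candidates. The strongest candidates of the replicates near each of these genes had summits more than 200 bp apart, so no mean over replicates is given.

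**Figure D5:**
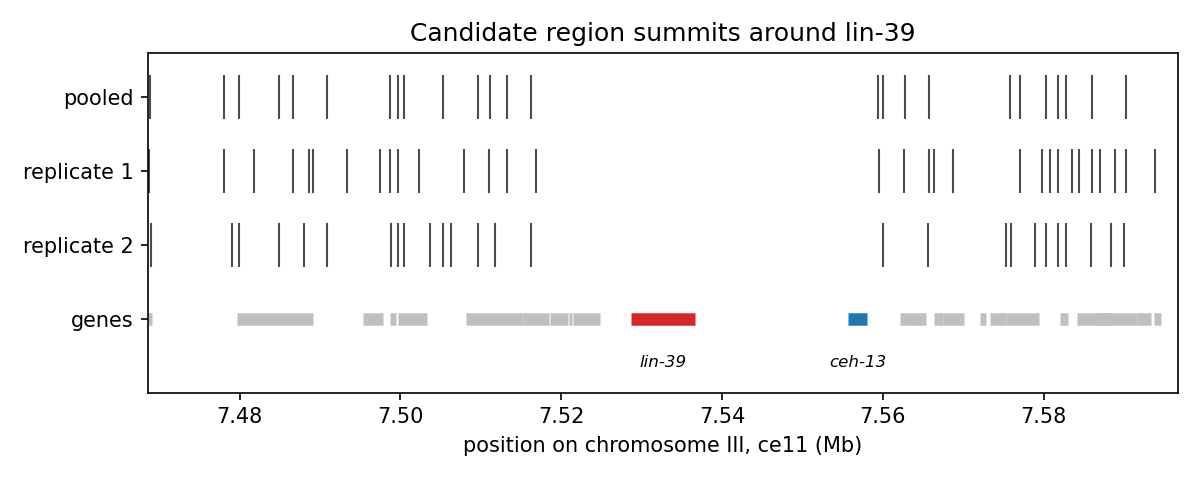
Summits of candidate regions (vertical lines) in the pooled list and in each replicate's list along chromosome III of build ce11 (x, Mb), with protein-coding genes below. The pooled list has no summit between 7516254 and 7559356, a stretch that holds *lin-39* in red and *ceh-13* in blue.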

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

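The restriction to peaks in the top 1000 of both replicates, the ce10 chromosome shares and the distance and build settings for peaks found in each replicate were chosen after seeing the data. Promoter share and replicate agreement kept their direction and their side of the threshold in every alternative run, with promoter shares from 28.2% for the 1000 highest pooled regions to 52.8% with a promoter of 2000 bp, and agreement from 13.1% over the 5000 highest regions to 39.8% on ce10. Rank correlation stayed between 0.0893 and 0.135. With the 1000 highest pooled regions, the number of chromosomes past the test fell from 2 to 1, the number of patterns rose from 1 to 3, the tRNA share was 0.9% and passed Fisher's exact test (p = 0.0096), and the share with TAATKR, 37.5%, moved from below to above its flanks without passing the test. With a motif window of 200 bp, 3 patterns passed. The number of gene lists past the test was 2, and became 1 for the upper part of the peaks split at the median signal, 3 for the 1000 highest pooled regions and 5 when the nearest gene on both sides was taken. Without one replicate or the other, it ranged from 1 to 2. With the peaks in the top 1000 of both replicates only, 4 chromosomes passed instead of 2, X among them at 33.1% (Fisher's exact adjusted p = 0.0091; 0.0322 to 0.128 over the other alternatives). The share of peaks in the top 1000 of both replicates was 72.4%, and became 65.0% with summits within 100 bp and 87.4% on ce10. The percentile of pooled candidates around *lin-39* was 1.72, and became 0.275 within 10000 bp and 21.1 within 50000 bp. The number of thresholded peaks was 163 and became 103 on ce10. The causes of these changes were not tested. Taking as many of the highest pooled regions as there are thresholded peaks gave the same set, so that setting tested nothing. No paired analysis was possible because there is 1 group.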

Other observations

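Tests chosen only after the results were seen are those of small RNA classes other than tRNA, of promoter share by chromosome, of GC content, of the 20 highest regions, of what accounts for the X share apart from the motif's presence at X peaks, and of control reads and spacing at *lin-39*. The recruitment motif was itself picked after the positions of the X peaks had been seen, and before any match was counted. The tests of ribosomal protein genes and of repeats were added after those patterns had been seen, and set before their own results.

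Spliced leader genes lay near some of the peaks. Of 6 small RNA classes, small nuclear RNA genes lay within 200 bp of 4 of the 163 peaks, 2.45% against 0.0704% of candidates (two-sided Fisher's exact test, adjusted p = 5.8e-05). They were *sls-2.1*, *sls-2.2* and *sls-2.4*, which encode SL2 spliced leader RNAs. As there were more peaks than genes, some peaks shared a gene, and the test counted them as independent. It was not repeated with overlapping peaks counted once. MicroRNA genes lay near 2 peaks, *mir-52* and *mir-5549* (Fisher's exact adjusted p = 0.0369). Peaks on X lay in promoters in 28.9% of cases and autosomal peaks in 47.5% (Fisher's exact p = 0.0348), remaining candidates differed in the same direction, at 18.1% and 23.6%, and X peaks did not pass against X candidates (p = 0.0776). GC content within 100 bp of the summit was 42.3% ± 7.32 (SD over 163 peaks), against 36.4% in the flanks and 33.9% in the remaining candidates.

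The share of peaks on X did not pass its planned test, but sites on X headed the list, with 11 of the 20 highest peaks. The 12-bp motif TCGCGCAGGGAG, known from recruitment sites of the dosage compensation complex, was present with at most 2 mismatches at 12 of 45 X peaks, 26.7% (15.96 to 41.04%), and at 2 of 118 autosomal peaks (Fisher's exact p = 3.4e-06), and at 7 of the 11 X peaks among the 20 highest; the share needed was set at 25%, and it was exactly 25% with 2 overlapping peaks counted once, 11 of 44, and below it at 22.2% with at most 1 mismatch, while with 3 mismatches 14.4% of autosomal peaks matched as well. Whether 1 replicate carries the X share stays open: it was at least 27.6% among the 163 highest regions of each and passed in both without adjustment (Fisher's exact p = 0.0432 and 0.0156), but only in replicate 2 after adjustment over chromosomes (p = 0.064 and 0.0322). Higher coverage of X in general stays open too, since the next 1000 regions after the 163 peaks had 23.3% (Fisher's exact p = 0.236), and the shares among the 20 highest regions, at least 55% in each replicate against 22.6% of the next 1000 pooled regions, restate what prompted the test and exclude nothing. A candidate explanation is that part of the X signal comes from dosage compensation sites, by open chromatin or otherwise; whether they account for all of it cannot be told apart from chance, because the X share of peaks without the motif was 22.1% and the excess had not passed its test to begin with.

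Ribosomal protein genes were more frequent at promoter peaks than at other promoter candidates, including those matched on GC content. Among promoter regions, 7 of 69 peaks lay at such a gene, 10.1%, against 0.328% of remaining promoter candidates (Fisher's exact p = 1.1e-08) and 0.906% of promoter candidates matched on GC content (p = 5.4e-05). The outcome over all promoter candidates was largely set by counts already seen. All 7 peaks were known to lie in promoters, and only 32 other such genes lay near candidates. The list had also been chosen because it stood out at these same peaks. Ribosomal protein genes are highly transcribed, and signal that follows transcription rather than LIN-39 may be present. A control alignment already entered the deposited signals, but its reads were not analysed here. No separate input, untagged strain or expression data were analysed either, so this explanation stays open, as does binding by LIN-39.

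The stretch without candidates around *lin-39* may reflect extra copies of the region in the control reads. It was at least 42641 bp long in all 3 lists and ranked 8 to 10 among 29994 stretches between candidates. This length does not test the explanation, because 27992 bp were already known to be empty when bounds of 20000 to 50000 bp were set, and chance spacing stays open for the same reason, with at most 0.98% of random positions on III in a stretch as long. Repeats made up 28.4 to 28.6% of the stretch in the 3 lists, at percentiles 22.3 to 23.3 of random windows on III. The stretch thus held no excess of repeats, which argues against a high repeat share as its cause. The bound set in advance for rejecting that cause, a share below that of 95% of the windows, was not reached. At *unc-119*, mutant in this strain, the stretch between candidates was at most 4033 bp. This gene was examined because the plan took the strain to carry extra copies of it too. Whether the transgene carries *unc-119* and whether the control came from this strain are not given in the sources used here. No biological explanation of the stretch around *lin-39* was tested.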
